A study of Arabidopsis thaliana with 15 samples.

How the data were processed

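Gene expression was measured in rosettes of 5 Arabidopsis genotypes with 3 libraries each, all labelled as biological replicates. Per the labels' protocols, plants grew 9 to a pot at 23 C with pots in random positions, and each sample pooled 5 rosettes from different pots. Libraries were made from 2 ug of total RNA with a stranded kit for polyadenylated RNA and sequenced on an Illumina HiSeq, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with TopHat2 2.1.0, counted per gene with HTSeq 0.6.1 and tested with edgeR, and the genome build was TAIR10. The counting mode, the strand setting, the trimming settings and the annotation version are not given in the sources used here. The deposited table holds whole-number read counts per gene with no normalisation, and it has no coordinates. Positions and products were taken from TAIR10.1, in which 32834 of the 33601 locus tags were found.

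The table ends with totals of reads that were assigned to no gene, and these stayed out of library sizes and tests. Relative to the reads in genes, 0.667 to 1.05% overlapped no feature, 1.63 to 6.67% were ambiguous and 2.37 to 6.62% were not uniquely placed. If the counting ignored strand, reads from genes that overlap on opposite strands cannot be told apart. Near-identical copies share reads that are then dropped or split: PDF1.2A, PDF1.2B, PDF1.2C and PDF1.3, LTP3 and LTP4, LHCB2.1 and LHCB2.2, the LHCB1 genes, BIP1 and BIP2, KIN1 and KIN2, GSTF6 and GSTF7, and the SAUR genes. Values of single members of these groups are therefore uncertain.

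Library totals ran from 9573567 to 16803904 gene counts, with 4.74 to 7.48% of counts in the 10 highest genes. No pair of replicates agreed within sampling noise, the chi-square per degree of freedom running from 2.75 to 15.3, so every library counted as 1 replicate.

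Genes with more than 1 CPM in at least 3 of the 15 libraries were kept, which left 18935. Counts were scaled by TMM (factors 0.937 to 1.08) and fitted with edgeR 4.0.16 in R 4.3.3, with all 15 libraries in 1 quasi-likelihood model of genotype. Contrasts were ref4-1, ref4-3, cdk8-1 and ref4-3 cdk8-1 against WT, ref4-3 cdk8-1 against each single mutant, ref4-3 against ref4-1, and the interaction of ref4-3 with cdk8-1. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and fold changes used a prior count of 0.125. The SE is the fold change over the square root of the F statistic. The median biological coefficient of variation was 6.96%. The p-values measure the spread between these samples, each a pool of 5 plants from 1 growth experiment as far as the labels tell.

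For genes at 0 counts in a whole group, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts in a group, the ratio of normalised counts is given with an exact 95% interval, which covers counting error only. Medians of lists with such members were also taken with the member at its bound.

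Lists of genes were chosen before the data were examined, as were the tests, the comparisons, the rule for named genes and most alternatives. There were 28 lists with 403 members, among them salicylic acid, phenylpropanoids and lignin, flavonoids and anthocyanins, Kelch F-box genes that degrade phenylalanine ammonia-lyase or chalcone synthase, Mediator subunits and jasmonate. Others were defensins and other jasmonate-ethylene defence, aliphatic and indolic glucosinolates with camalexin, photosynthesis, cell expansion, auxin response, cell cycle, heat shock, endoplasmic reticulum stress, cold and abscisic acid, circadian clock, flowering time, phosphate starvation, iron, leaf senescence, oxidative stress and reference genes. Cell type markers were those of xylem, phloem and guard cells, root, seed storage and flower organs. Of these, 25 had enough measured members for a test. Each was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists in each comparison. The estimated correlation and fry were alternatives. The direction of every list past camera was also taken with other scaling.

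MED5B, CDK8 and DJC66 are named in the report whatever their result. Otherwise named genes are the 6 greatest rises and 6 greatest falls among called genes with a mean of at least 5 CPM and no overlap of the groups, in each comparison with WT and in ref4-3 cdk8-1 against ref4-3. Of genes without a difference, 10% show no overlap by chance with 3 against 3. In ref4-3 cdk8-1 against cdk8-1 and in ref4-3 against ref4-1 it was 3 and 3, and for the interaction 3 and 3 with no condition on overlap. To these come the up to 3 members with the smallest adjusted p of every list that had a called member.

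The overlaps of comparisons against the same WT libraries were set against 20 simulations of unchanged groups and against independent lists. Jackknife SEs came from leaving out each library in turn. The fit was tested on simulated counts with 200 changed genes among 18935. It recovered 59.7, 80.6 and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold for ref4-3 against WT, and 65.7, 83.6 and 97.0% for ref4-3 cdk8-1 against ref4-3. For the interaction it recovered 37.3, 70.1 and 93.9%. False calls were 5.39, 0.606 and 2.90% of all calls in these 3 steps. In a simulated list test of uncorrelated genes for ref4-3 against WT, camera found the 1 list raised 1.5-fold and called 0 others.

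Alternatives were DESeq2 1.42.0 and voom in place of edgeR, size factors of the relative log expression kind in place of TMM, no filter beyond 1 count, a filter of 5 CPM, a replicate block, a fit of the compared groups only, a 2-fold minimum, leaving out each library in turn, and other list tests. Leaving out ref4-1 replicate 3 from comparisons without ref4-1 was added after the data were seen.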

Results

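The transcriptome of Arabidopsis thaliana (accession Col-0) rosettes was measured by sequencing of polyadenylated RNA in 5 genotypes with 3 libraries each. The genotypes were the wild type (WT), the MED5B mutants ref4-1 and ref4-3, the CDK8 mutant cdk8-1, and the double mutant ref4-3 cdk8-1. MED5B and CDK8 are subunits of Mediator, the complex that links transcription factors to RNA polymerase II, and CDK8 is the kinase of its detachable module. Every library came from 5 pooled whole rosettes of 20 days, taken 6.5 h after subjective dawn in a cycle of 16 h light and 8 h dark. Total gene counts per library were 12343266 to 12623559 in WT, 9573567 to 16803904 in ref4-1 and 11757969 to 13445046 in ref4-3. They were 11325163 to 12417532 in cdk8-1 and 13418083 to 15080524 in ref4-3 cdk8-1. Thus 1 count equalled 0.0595 to 0.104 CPM. Levels are given as normalised CPM, mean ± SD, n = 3. Changes are log2 fold changes ± SE with n = 3 in each group, and adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over 18935 genes. Preset gene lists were compared with all other genes by camera, adjusted over 25 lists. "Rose" and "fell" refer to genes with adjusted p under 0.05, and p-values measure the spread between these samples.

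The mutated genes were examined first in every genotype. CDK8 (AT5G63610, chromosome 5, 25463362 to 25465922, TAIR10.1) stood at 19.5 ± 1.28 CPM in WT, 18.16 ± 1.80 in ref4-1, 22.1 ± 0.788 in ref4-3, 4.51 ± 0.170 in cdk8-1 and 5.41 ± 1.103 in ref4-3 cdk8-1. It thus fell in both genotypes that carry cdk8-1, with -2.11 ± 0.13 in cdk8-1 (adjusted p = 1.55e-10) and -1.84 ± 0.12 in ref4-3 cdk8-1 (adjusted p = 4.37e-11). MED5B (AT2G48110, chromosome 2, 19673293 to 19679711), whose ref4 alleles are point mutations, stood at 24.8 ± 3.61 CPM in WT, 28.3 ± 1.31 in ref4-1, 29.9 ± 0.921 in ref4-3, 25.2 ± 2.39 in cdk8-1 and 23.1 ± 0.496 in ref4-3 cdk8-1. Its rise in ref4-3 was small (0.27 ± 0.091, adjusted p = 0.0203), and a transcript level cannot check a point mutation. DJC66 (AT3G13310, chromosome 3, 4310544 to 4311629), which encodes a chaperone with a DnaJ domain, went from 14.96 ± 1.81 CPM in WT to 337 ± 57.1 in ref4-1, 353 ± 12.1 in ref4-3 and 221 ± 14.96 in ref4-3 cdk8-1, and stood at 12.5 ± 0.471 in cdk8-1.

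**Figure D1:**
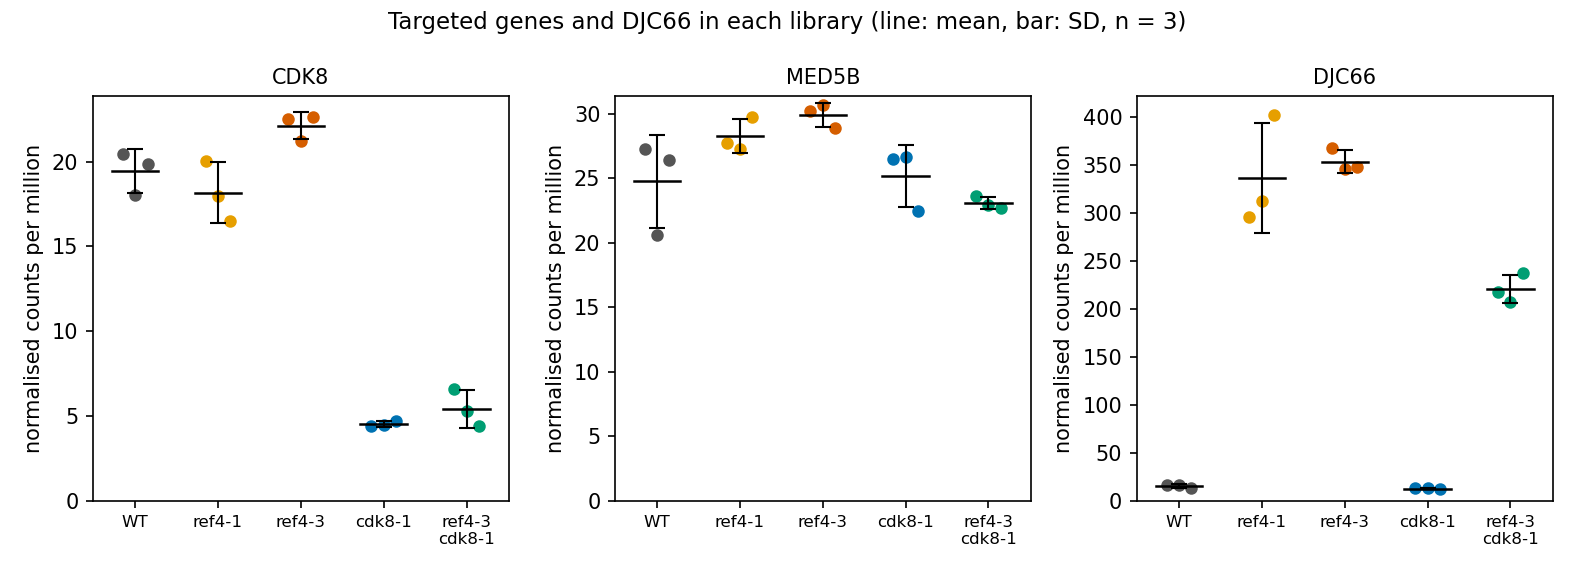
Normalised CPM of CDK8, MED5B and DJC66 in each of the 15 libraries, by genotype. Points are libraries, lines are means of 3 libraries and bars are SD; CDK8 is lower in the 6 libraries that carry cdk8-1, with a highest value of 6.58 CPM against a lowest WT value of 18.02 CPM.

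The comparison of ref4-1 with WT asked which transcripts change with this MED5B allele, known for low levels of phenylpropanoids. Phenylpropanoid and lignin genes fell as a list while the Kelch F-box genes that mark phenylalanine ammonia-lyase for degradation rose: 4CL1 and COMT1 changed by -1.11 ± 0.073 and -1.18 ± 0.074, KFB39 and KFB50 by 5.06 ± 0.12 and 1.35 ± 0.065. The flavonoid gene F3H (2.22 ± 0.19) and, from the list of the defence hormone salicylic acid, CBP60g (1.22 ± 0.13) and SARD1 (1.18 ± 0.13) rose. PDF1.2 and PDF1.3 defensins fell from high WT levels, PDF1.3 from 613 ± 158 to 15.8 ± 2.69 CPM. Light-harvesting LHCB1.2 (-0.99 ± 0.082) and auxin-response IAA3 (-0.62 ± 0.083) fell as well. In all, 3975 genes were called (2034 higher, 1941 lower), 784 of them at least 2-fold.

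The greatest rises among well expressed genes in ref4-1 were those of the defensin-like AT3G59930 (6.61 ± 0.16), the uncharacterised AT4G10860 (6.06 ± 0.50), the early light-induced ELIP1 (5.14 ± 0.30), KFB39 (5.06 ± 0.12), DJC66 (4.49 ± 0.11) and the subtilase SBT3.3 (3.46 ± 0.24). The greatest falls were those of MRD1 (-5.43 ± 0.24), PDF1.3 (-5.26 ± 0.31), PDF1.2B (-4.35 ± 0.31), PDF1.2C (-4.35 ± 0.33), the acyltransferase AT5G61160 (-3.99 ± 0.23) and PDF1.2A (-3.96 ± 0.40). The PDF1.2 and PDF1.3 sequences are near-identical, so their counts are uncertain one by one.

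Of the salicylic acid genes, 20 of 30 rose (23 adjusted over the list alone, median 0.68, adjusted p = 4.72e-12, adjusted p = 0.0876 with an estimated correlation), with CBP60g, SARD4 (0.79 ± 0.097) and SARD1 at the smallest adjusted p. In the phenylpropanoid list 2 of 21 rose and 15 fell (3 and 15 adjusted over the list alone, median -0.62, adjusted p = 4.72e-12), and the sinapate glucosyltransferase UGT84A2 (2.16 ± 0.084) was the strongest riser. Among Kelch F-box genes 4 of 5 rose and 1 fell (4 and 1 adjusted over the list alone, median 1.35, adjusted p = 1.61e-21), the fall being that of KFB-CHS (-1.36 ± 0.10), which targets chalcone synthase. Of the flavonoid genes 13 of 19 rose (15 adjusted over the list alone, median 1.22, adjusted p = 4.72e-12, adjusted p = 0.0876 with an estimated correlation), including FLS1 (1.75 ± 0.13). The regulator MYB11 had a count ratio to WT of 26.1 (95% counting interval 8.64 to 129). For endoplasmic reticulum stress 8 of 9 rose (8 adjusted over the list alone, median 0.29, adjusted p = 0.000205, adjusted p = 0.152 with an estimated correlation), as with BIP2 (0.41 ± 0.071) and BIP3 (1.28 ± 0.21). In the cold and abscisic acid list 7 of 15 rose (8, and 1 fell, adjusted over the list alone, median 0.84, adjusted p = 2.74e-06, adjusted p = 0.0876 with an estimated correlation), led by COR15B (1.305 ± 0.10) and NCED3 (1.26 ± 0.20). Of the senescence genes 7 of 13 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.00765, adjusted p = 0.0876 with an estimated correlation). The NAC regulator ORE1 (2.13 ± 0.21) rose and the dark-induced AT4G35770 (-1.66 ± 0.20) fell.

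Among defensin and ethylene-jasmonate defence genes in ref4-1, 1 of 10 rose and 6 fell (1 and 7 adjusted over the list alone, median -1.18, adjusted p = 4.16e-07, adjusted p = 0.0876 with an estimated correlation), with PR4 (-1.41 ± 0.13) beside the defensins. In indolic glucosinolate and camalexin synthesis 8 of 14 fell (8 adjusted over the list alone, median -0.50, adjusted p = 2.22e-05, adjusted p = 0.0876 with an estimated correlation), as with CYP81F2 (-1.80 ± 0.26) and MYB51 (-0.82 ± 0.13). In aliphatic glucosinolate synthesis 3 of 14 fell (3 adjusted over the list alone, median -0.15, adjusted p = 0.0467, adjusted p = 0.459 with an estimated correlation), as with CYP83A1 (-0.37 ± 0.077). Of the photosynthesis genes 19 of 23 fell (19 adjusted over the list alone), LHCB1.2 and LHCB2.1 (-0.81 ± 0.078) first (median -0.47, adjusted p = 8.98e-17, adjusted p = 0.0965 with an estimated correlation). Of the cell expansion genes 1 of 14 rose and 7 fell (1 and 10 adjusted over the list alone, median -0.31, adjusted p = 0.000793, adjusted p = 0.253 with an estimated correlation). XTH17 (-2.84 ± 0.39) fell and the expansin EXPA10 (1.04 ± 0.070) rose. For auxin response 7 of 18 fell (9 adjusted over the list alone, median -0.60, adjusted p = 2.22e-05, adjusted p = 0.0876 with an estimated correlation), as with IAA19 (-1.41 ± 0.24). In the heat shock list 1 of 14 rose and 4 fell (2 and 5 adjusted over the list alone, median -0.25, adjusted p = 0.0281, adjusted p = 0.276 with an estimated correlation), as with HSP70 (-0.93 ± 0.14). Of the xylem markers, a cell type list, 5 of 13 fell (6 adjusted over the list alone, median -0.42, adjusted p = 0.0234, adjusted p = 0.276 with an estimated correlation), as with XCP2 (-0.58 ± 0.13). The phenylpropanoid and Kelch F-box lists kept an adjusted p under 0.05 with an estimated correlation. Library ref4-1 replicate 3 stood apart from the other 2 of its group, with a chi-square per degree of freedom of 15.3 and 11.97 against them and 6.62% of reads not uniquely placed. Without it, 4018 genes were called in ref4-1.

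The comparison of ref4-3 with WT asked the same of the second MED5B allele, which is known to dwarf the plant. The light-harvesting genes LHCB1.2 (-1.62 ± 0.083), LHCB2.1 (-1.54 ± 0.080) and LHCB2.2 (-1.38 ± 0.080) fell, while cold and abscisic acid genes rose, such as RD29A (1.60 ± 0.085) and COR15B (2.35 ± 0.10). KFB39 went from 7.84 ± 1.32 CPM in WT to 274 ± 17.61 in ref4-3, and 4CL1 (-1.37 ± 0.074) and SNG1 (-1.24 ± 0.069), the enzyme that makes sinapoylmalate, fell. In all 7544 genes were called (3821 higher, 3723 lower), 1490 of them 2-fold.

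At the top of the ref4-3 changes were ELIP1 (6.95 ± 0.26), AT3G59930 (6.36 ± 0.16), the lipid transfer proteins LTP4 (6.31 ± 0.47), LTP3 (5.99 ± 0.31) and AT2G37870 (5.84 ± 0.42), and the ATPase gene DAA1, whose count ratio to WT was 147 (95% counting interval 49.9 to 714). LTP3 and LTP4 are near-identical neighbours, and their split is uncertain. At the bottom were PDF1.2C (-6.45 ± 0.39), PDF1.3 (-6.28 ± 0.34), PDF1.2B (-5.87 ± 0.37), PDF1.2A (-5.42 ± 0.43), AT5G61160 (-4.90 ± 0.26) and the lectin AT3G15356 (-4.73 ± 0.24).

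Salicylic acid genes in ref4-3 were higher as a list: 21 of 30 rose and 2 fell (21 and 4 adjusted over the list alone, median 0.80, adjusted p = 8.58e-07, adjusted p = 0.200 with an estimated correlation), with SARD4 (1.01 ± 0.096), CBP60g (1.302 ± 0.13) and SARD1 (1.404 ± 0.13) first. Of the phenylpropanoid genes 3 of 21 rose and 15 fell (3 and 16 adjusted over the list alone, median -0.71, adjusted p = 3.88e-09, adjusted p = 0.0571 with an estimated correlation), UGT84A2 (2.59 ± 0.084) being the strongest riser. In the Kelch F-box list 4 of 5 rose and 1 fell (4 and 1 adjusted over the list alone, median 1.395, adjusted p = 3.59e-11), as with KFB50 (1.395 ± 0.065) and KFB-CHS (-1.72 ± 0.10). Of the flavonoid genes 17 of 19 rose (18, and 1 fell, adjusted over the list alone, median 1.71, adjusted p = 7.33e-11, adjusted p = 0.0947 with an estimated correlation), including F3H (2.92 ± 0.19). MYB11 had a count ratio of 35.9 (95% counting interval 12.002 to 177). In the cold and abscisic acid list 13 of 15 rose (14 adjusted over the list alone, median 1.64, adjusted p = 9.77e-19). For endoplasmic reticulum stress 7 of 9 rose (7 adjusted over the list alone, median 0.27, adjusted p = 0.00408, adjusted p = 0.2798 with an estimated correlation), as with PDIL1-1 (0.52 ± 0.066). For senescence 9 of 13 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.60, adjusted p = 0.00383, adjusted p = 0.0716 with an estimated correlation), as with ORE1 (2.75 ± 0.20) and NAP (2.96 ± 0.37).

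Lower lists in ref4-3 were led by photosynthesis, where 23 of 23 fell (23 adjusted over the list alone, median -0.82, adjusted p = 3.94e-27, adjusted p = 0.0628 with an estimated correlation). Defensin and ethylene-jasmonate defence genes fell, as 1 of 10 rose and 7 fell (2 and 7 adjusted over the list alone, median -2.31, adjusted p = 1.44e-06, adjusted p = 0.0628 with an estimated correlation), with PR4 (-2.16 ± 0.13) among them. Of the jasmonate genes 9 of 21 fell (10 adjusted over the list alone, median -0.92, adjusted p = 0.00733, adjusted p = 0.604 with an estimated correlation), as with JAZ8 (-2.03 ± 0.44). In indolic glucosinolate synthesis 11 of 14 fell (12 adjusted over the list alone, median -0.85, adjusted p = 3.01e-06, adjusted p = 0.0628 with an estimated correlation), as with UGT74B1 (-0.74 ± 0.071) and IGMT1 (-2.04 ± 0.20). In cell expansion 1 of 14 rose and 11 fell (1 and 11 adjusted over the list alone, median -0.52, adjusted p = 9.56e-06, adjusted p = 0.131 with an estimated correlation), as with EXPA11 (-1.38 ± 0.13). In auxin response 13 of 18 fell (16 adjusted over the list alone, median -0.997, adjusted p = 5.68e-06, adjusted p = 0.0628 with an estimated correlation), as with IAA19 (-2.07 ± 0.26). IAA6 left 1 count in ref4-3, a WT to ref4-3 ratio of 82.0 (95% counting interval 14.3 to 3282). Kelch F-box and cold genes kept an adjusted p under 0.05 with an estimated correlation.

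Both alleles called 1793 of the same genes higher and 1721 lower, and 3 in opposite directions. Independent lists of these sizes would share 410 and 382 genes, and unchanged groups simulated 20 times against the same WT libraries shared 0. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.896 (jackknife SE 0.0386), against 0.523 in the simulation, and their covariance was 0.312 against 0.0210. Part of the excess in shared genes and in r may come from the shared WT libraries, since 3 cannot be split.

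The direct comparison of ref4-3 with ref4-1 asked where the alleles differ. Cold and abscisic acid genes were higher in ref4-3, with RD29A (1.24 ± 0.084), ERD10 (0.65 ± 0.067) and COR15B (1.05 ± 0.10), and light-harvesting LHCB2.1 (-0.73 ± 0.079) and LHCB2.2 (-0.64 ± 0.079) were lower. The greatest differences were at MRD1, at 0.791 ± 0.780 CPM in ref4-1 and 30.6 ± 3.32 in ref4-3, at AT5G35935, at 1.87 ± 0.164 and 24.1 ± 1.32 CPM, and at DAA1 (3.05 ± 0.30). WT stood at 29.0 ± 2.05 CPM for MRD1 and 17.1 ± 0.885 for AT5G35935, so ref4-1 was the low line at both, and differences of that line outside MED5B were not tested. On the other side stood PDF1.2C (-2.11 ± 0.40), the terpene synthase TPS03 (-2.09 ± 0.46) and QQS (-1.94 ± 0.21). DJC66 differed by 0.072 ± 0.090 (adjusted p = 0.661). In all 2095 genes were called (882 higher in ref4-3, 1213 lower), 187 of them 2-fold. The count was 823 when only these 6 libraries were fitted and 1040 without ref4-3 replicate 3.

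No salicylic acid gene of 30 passed edgeR's test between the alleles, with 2095 calls over all genes; at an unadjusted p under 0.05 edgeR had 2 higher and 2 lower, and DESeq2 and voom called 0. In the phenylpropanoid list 2 of 21 were called higher and 5 lower (2 and 7 adjusted over the list alone), as with SNG1 (-0.51 ± 0.069) and UGT84A2 (0.43 ± 0.076; adjusted p = 0.110 for the list). Among Kelch F-box genes 1 of 5 was called lower (1 adjusted over the list alone), which was KFB-CHS (-0.36 ± 0.11; adjusted p = 0.928). In the cold and abscisic acid list 12 of 15 were called higher (13 adjusted over the list alone, median 1.05, adjusted p = 3.30e-30). Of the photosynthesis genes 19 of 23 were called lower (20 adjusted over the list alone, median -0.39, adjusted p = 2.16e-21, adjusted p = 0.3004 with an estimated correlation). In cell expansion 6 of 14 were called lower (7 adjusted over the list alone, median -0.31, adjusted p = 0.000269, adjusted p = 0.3004 with an estimated correlation), as with EXPA1 (-0.61 ± 0.12). In auxin response 3 of 18 were called lower (6 adjusted over the list alone, median -0.53, adjusted p = 0.00408, adjusted p = 0.3004 with an estimated correlation), as with IAA17 (-0.53 ± 0.10). In indolic glucosinolate synthesis 3 of 14 were called lower (5 adjusted over the list alone, median -0.39, adjusted p = 0.00261, adjusted p = 0.3004 with an estimated correlation), as with IGMT1 (-1.06 ± 0.22). Of the defensin genes 3 of 10 were called lower (7 adjusted over the list alone, median -0.89, adjusted p = 0.00161, adjusted p = 0.3004 with an estimated correlation), as with PR4 (-0.75 ± 0.13). In the flavonoid list 2 of 19 were called higher (2 adjusted over the list alone, median 0.48, adjusted p = 0.00136, adjusted p = 0.564 with an estimated correlation), as with F3H (0.70 ± 0.15). The jasmonate list was lower in ref4-3 (median -0.70, adjusted p = 0.00129, adjusted p = 0.693 with an estimated correlation), with no member called by edgeR, 8 lower at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by voom.

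The comparison of cdk8-1 with WT asked what the loss of the kinase changes on its own. Salicylic acid genes fell, among them WRKY38 (-2.23 ± 0.25), EDS5 (-0.92 ± 0.13), a transporter needed for its synthesis, and UGT76B1 (-2.06 ± 0.30). PDF1.2 and PDF1.3 defensins fell, PDF1.3 to 1.64 ± 1.02 CPM. Light-harvesting LHCB2.1 (1.36 ± 0.079) and LHCB2.2 (1.24 ± 0.079) rose, as did cold-regulated COR47 (0.82 ± 0.060) and COR15B (1.13 ± 0.10). Heat shock genes fell, HSP70 (-2.48 ± 0.18) and HSFA2 (-2.92 ± 0.39). In all 3712 genes were called (1530 higher, 2182 lower), and 888 changed 2-fold, of which 192 were higher and 696 lower.

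A pair of genes far from CDK8 lost nearly all of their transcript in cdk8-1. MRD1 (chromosome 1, 19963047 to 19964712) left 1 count, so WT exceeded cdk8-1 by a count ratio of 986 (95% counting interval 176 to 38963), and AT3G57880 (chromosome 3, 21430922 to 21434648), a predicted lipid-binding protein, went from 20.98 ± 1.08 to 0.267 ± 0.0966 CPM. Also among the greatest falls were PDF1.3 (-8.53 ± 0.42), PDF1.2B (-7.79 ± 0.47), PDF1.2C (-7.38 ± 0.43) and PDF1.2A (-6.10 ± 0.46). The greatest rises were those of AT1G11070 (3.504 ± 0.18), the protease AT1G62290 (3.29 ± 0.18), the cold-regulated KIN1 (1.99 ± 0.33), XTH31 (1.90 ± 0.090), LHCB2.3 (1.86 ± 0.097) and AT5G57785 (1.85 ± 0.22). MRD1 lies across an opposite-strand gene, HEI10 (-1.51 ± 0.26; chosen after its value was seen), and reads of the pair may not be separated.

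Of the salicylic acid genes in cdk8-1, 23 of 30 fell (25 adjusted over the list alone, median -1.14, adjusted p = 5.06e-17). In the phenylpropanoid list 3 of 21 rose and 5 fell (5 and 5 adjusted over the list alone), with C4H (-0.53 ± 0.072) and 4CL3 (0.68 ± 0.10); its median was 0.043, its mean -0.028, and it did not pass (adjusted p = 0.793). In the Kelch F-box list 2 of 5 fell (2 adjusted over the list alone), as with KFB1 (-0.66 ± 0.15), and it did not pass either (median -0.027, adjusted p = 0.444). For defensins 7 of 10 fell (8 adjusted over the list alone, median -1.96, adjusted p = 1.23e-17), as with PR4 (-2.61 ± 0.13). Of the jasmonate genes 6 of 21 fell (11 adjusted over the list alone, median -0.83, adjusted p = 0.000398, adjusted p = 0.570 with an estimated correlation), as with LOX2 (-0.99 ± 0.22). In indolic glucosinolate and camalexin synthesis 9 of 14 fell (9 adjusted over the list alone, median -0.50, adjusted p = 1.31e-10), as with MYB51 (-1.93 ± 0.15) and IGMT1 (-2.71 ± 0.23). In the heat shock list 8 of 14 fell (10 adjusted over the list alone, median -1.03, adjusted p = 9.01e-11), as with HSP90.1 (-1.59 ± 0.17). The median was the same with the small heat shock gene AT1G53540, at 0 counts, at its bound, and -0.48 without it. For oxidative stress 8 of 12 fell (9, and 1 rose, adjusted over the list alone, median -0.96, adjusted p = 3.50e-09), as with OM66 (-2.41 ± 0.17) and ZAT12 (-1.98 ± 0.27). Of the senescence genes 6 of 13 fell (7 adjusted over the list alone, median -0.62, adjusted p = 0.000256), as with WRKY53 (-1.98 ± 0.28). For endoplasmic reticulum stress 4 of 9 fell (4 adjusted over the list alone, median -0.15, adjusted p = 0.00192, adjusted p = 0.240 with an estimated correlation), as with BIP3 (-2.92 ± 0.36).

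Higher in cdk8-1 was the photosynthesis list, where 14 of 23 rose (17 adjusted over the list alone, median 0.28, adjusted p = 1.14e-11, adjusted p = 0.209 with an estimated correlation), as with LHCB3 (0.59 ± 0.077). In the cold and abscisic acid list 10 of 15 rose (10 adjusted over the list alone, median 0.95, adjusted p = 1.88e-11), as with RD29A (0.80 ± 0.084). For auxin response 11 of 18 rose and 3 fell (11 and 4 adjusted over the list alone, median 0.56, adjusted p = 0.000398, adjusted p = 0.112 with an estimated correlation), as with IAA17 (0.89 ± 0.095) and GH3.6 (0.88 ± 0.12). Of the cell cycle genes 3 of 17 rose (3 adjusted over the list alone, median 0.22, adjusted p = 0.00721, adjusted p = 0.220 with an estimated correlation), as with CDKB1;1 (0.52 ± 0.11). Of the flavonoid genes 4 of 19 rose (5 adjusted over the list alone, median 0.18, adjusted p = 0.0160, adjusted p = 0.582 with an estimated correlation), as with FLS1 (1.36 ± 0.13). Of the phosphate starvation genes 3 of 5 rose (4 adjusted over the list alone, median 0.68, adjusted p = 0.000306, adjusted p = 0.0556 with an estimated correlation), as with SPX1 (0.96 ± 0.13). Here 7 lists kept an adjusted p under 0.05 with an estimated correlation.

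Both cdk8-1 and ref4-3 called 379 genes higher, 623 lower and 1076 opposite (independent lists: 309, 429 and not computed). No preferred direction follows. Across genes, log2 fold changes correlated at 0.0557 (jackknife SE 0.0599) against 0.497 for unchanged groups simulated with the same WT libraries. The covariance was 0.0213 against 0.0208.

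The double mutant ref4-3 cdk8-1 was first set against WT, to ask how far its transcriptome lies from the wild type. Cold and abscisic acid genes rose, RD29A (3.16 ± 0.089), COR47 (1.83 ± 0.061) and ERD10 (1.82 ± 0.069), and RD29B went from 0.255 ± 0.0838 to 80.2 ± 4.99 CPM. PDF1.2 and PDF1.3 defensins fell, PDF1.2A from 1198 ± 257 to 1.27 ± 0.615 CPM, while the defensin-like AT3G59930 (4.78 ± 0.18) rose. The salicylic acid genes EDS5 (-2.52 ± 0.14) and WRKY38 (-3.71 ± 0.29) fell, as did the lignin genes CAD4 (-1.49 ± 0.078) and 4CL1 (-1.34 ± 0.073). In all 8053 genes were called (3948 higher, 4105 lower), 1854 of them 2-fold.

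Late embryogenesis abundant LEA7, at 0 counts in WT, was at least 174-fold higher, and the kinase gene WNK9 and DAA1 had count ratios of 208 (95% counting interval 57.4 to 1724) and 997 (341 to 4839). The other greatest rises were RD29B (8.24 ± 0.37), LTP4 (8.01 ± 0.42) and LTP3 (7.23 ± 0.30). PDF1.2B left 2 counts, a WT to double mutant ratio of 3161 (95% counting interval 875 to 26112). PDF1.2C (-11.87 ± 0.61), PDF1.3 (-11.63 ± 0.53), PDF1.2A (-9.90 ± 0.60), the efflux carrier AT3G23550 (-7.82 ± 0.27) and AT5G61160 (-7.42 ± 0.34) completed the falls.

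Of the salicylic acid genes in the double mutant against WT, 1 of 30 rose and 24 fell (1 and 24 adjusted over the list alone, median -1.35, adjusted p = 9.82e-11, adjusted p = 0.120 with an estimated correlation), as with UGT76B1 (-3.11 ± 0.33). For phenylpropanoids 2 of 21 rose and 17 fell (2 and 18 adjusted over the list alone, median -0.65, adjusted p = 1.79e-07, adjusted p = 0.0810 with an estimated correlation), the riser with the smallest adjusted p being UGT84A2 (1.51 ± 0.084). In the Kelch F-box list 3 of 5 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.91, adjusted p = 0.000329, adjusted p = 0.144 with an estimated correlation), as with KFB39 (4.28 ± 0.12) and KFB-CHS (-1.85 ± 0.10). Of the jasmonate genes 20 of 21 fell (20 adjusted over the list alone, median -2.38, adjusted p = 1.98e-08, adjusted p = 0.274 with an estimated correlation), as with LOX2 (-2.20 ± 0.23) and CYP94C1 (-4.26 ± 0.55). For defensins 7 of 10 fell (7 adjusted over the list alone, median -3.45, adjusted p = 4.22e-12), as with ORA59 (-2.90 ± 0.24). In indolic glucosinolate synthesis 12 of 14 fell (13 adjusted over the list alone, median -1.41, adjusted p = 4.22e-12), as with MYB51 (-2.26 ± 0.14). Of the endoplasmic reticulum stress genes 7 of 9 fell (8 adjusted over the list alone, median -0.49, adjusted p = 0.000183, adjusted p = 0.148 with an estimated correlation), as with CNX1 (-0.60 ± 0.074). In the heat shock list 1 of 14 rose and 10 fell (2 and 10 adjusted over the list alone, median -0.996, adjusted p = 0.00267, adjusted p = 0.159 with an estimated correlation), as with HSFA2 (-3.05 ± 0.37). AT1G53540 at 0 counts was at least 19.3-fold lower, and the median was the same at that bound and -0.53 without it. Of the oxidative stress genes 2 of 12 rose and 5 fell (2 and 5 adjusted over the list alone, median -0.46, adjusted p = 0.00558, adjusted p = 0.178 with an estimated correlation), as with OM66 (-2.94 ± 0.17). For cell expansion 1 of 14 rose and 7 fell (1 and 8 adjusted over the list alone, median -0.28, adjusted p = 0.0421, adjusted p = 0.445 with an estimated correlation), as with XTH9 (-1.21 ± 0.091). For the cell cycle 1 of 17 rose and 9 fell (1 and 9 adjusted over the list alone, median -0.29, adjusted p = 0.0342, adjusted p = 0.282 with an estimated correlation), as with KN (-0.60 ± 0.075).

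Higher than WT in the double mutant was the cold and abscisic acid list, where 14 of 15 rose (14 adjusted over the list alone, median 2.89, adjusted p = 8.69e-48). In the flavonoid list 10 of 19 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.84, adjusted p = 6.27e-05, adjusted p = 0.274 with an estimated correlation), as with FLS1 (2.39 ± 0.13) and MYB111 (2.38 ± 0.18). Of the circadian clock genes 9 of 16 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.32, adjusted p = 0.0126, adjusted p = 0.0924 with an estimated correlation), as with LNK1 (1.12 ± 0.069). Of the phosphate starvation genes 3 of 5 rose (4, and 1 fell, adjusted over the list alone, median 0.92, adjusted p = 0.000510, adjusted p = 0.0924 with an estimated correlation), as with PAP17 (1.90 ± 0.093). Of the photosynthesis genes 3 of 23 rose and 12 fell (3 and 13 adjusted over the list alone), and the list did not pass (adjusted p = 0.124). The defensin, indolic glucosinolate and cold lists kept an adjusted p under 0.05 with an estimated correlation. MYB11 had a count ratio of 19.0 to WT (95% counting interval 6.23 to 94.2).

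**Figure D2:**
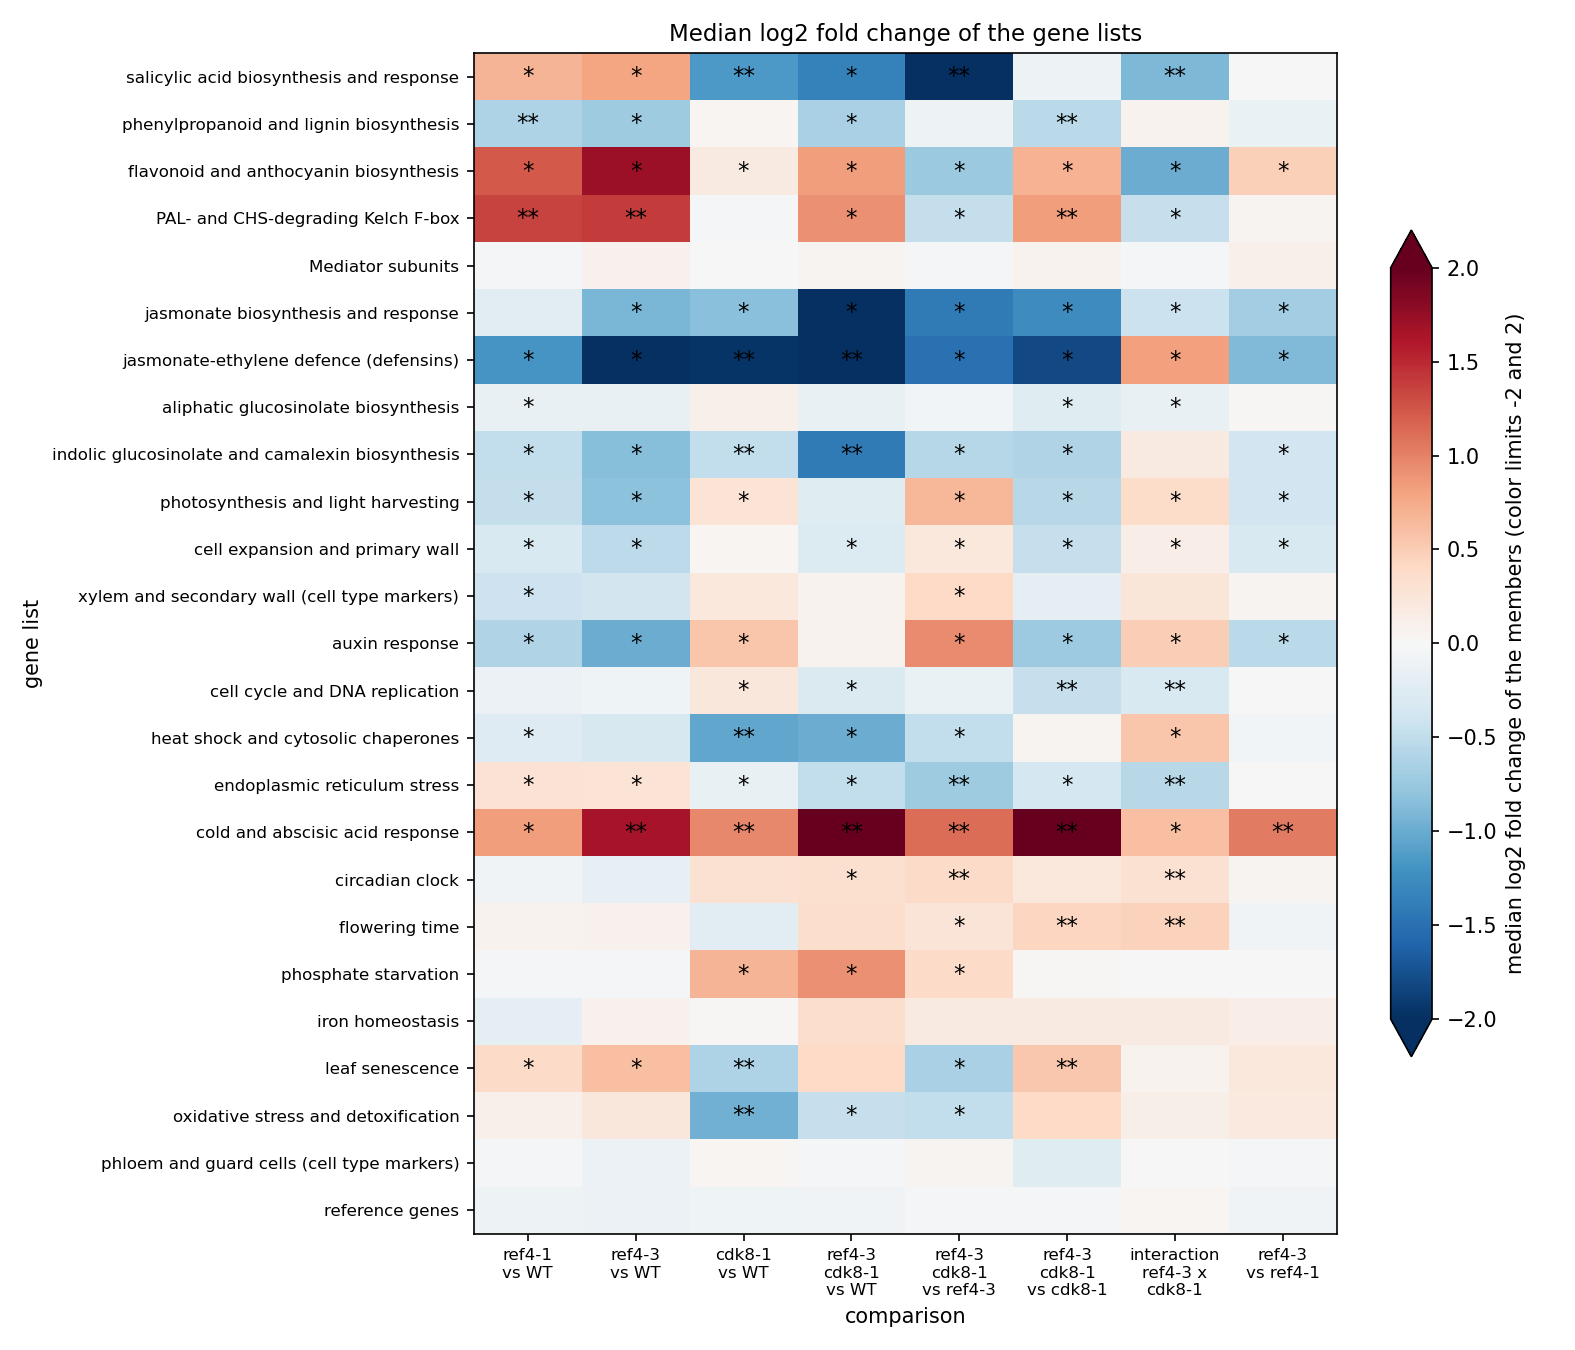
Median log2 fold change of 25 preset gene lists in the 8 comparisons, as a heat map with colour limits at -2 and 2. One asterisk marks camera adjusted p under 0.05 and a pair of them also with an estimated correlation; the salicylic acid list is at 0.80 in ref4-3 and -1.35 in ref4-3 cdk8-1 against WT.

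Comparing ref4-3 cdk8-1 with ref4-3 asked what cdk8-1 changes in ref4-3. Salicylic acid genes fell in the double mutant, SARD1 from 63.4 ± 8.46 to 8.03 ± 0.986 CPM (-2.98 ± 0.15), as did WRKY38 (-4.56 ± 0.26). Light-harvesting LHCB2.1 (2.28 ± 0.082) and LHCB1.2 (1.38 ± 0.083) rose, against their fall in ref4-3. KFB39 (-0.85 ± 0.093) and DJC66 (-0.68 ± 0.091) fell and stayed above WT. SNG1 (1.06 ± 0.069) rose and UGT84A2 (-1.08 ± 0.077) fell. In all 6183 genes were called (3022 higher, 3161 lower), 1413 of them 2-fold.

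Among single genes the greatest rises were AT1G67105 (5.76 ± 0.33), AT1G11070 (4.42 ± 0.21), AT1G62510 (4.31 ± 0.22), the late embryogenesis abundant AT3G17520 (3.31 ± 0.40), RD29B (2.95 ± 0.20) and AT2G16367 (2.88 ± 0.25). The falls were led by AT2G44240, with a ref4-3 to double mutant count ratio of 383 (95% counting interval 106 to 3170). Next were AT4G01390 (-6.18 ± 0.38), LUP5 (-5.86 ± 0.59), AT4G03450 (-5.45 ± 0.38), the chaperone BIP3 (-5.37 ± 0.31) and the glucanase BG3 (-5.20 ± 0.46).

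Of the salicylic acid genes 29 of 30 fell (29 adjusted over the list alone, median -2.18, adjusted p = 3.47e-40), as with SARD4 (-1.39 ± 0.097). In the phenylpropanoid list 7 of 21 rose and 5 fell (7 and 5 adjusted over the list alone), as with REF1 (-0.98 ± 0.086); its median was -0.094, its mean -0.043 and its adjusted p = 0.879. In the Kelch F-box list 3 of 5 fell (3 adjusted over the list alone, median -0.48, adjusted p = 0.000786, adjusted p = 0.146 with an estimated correlation), as with KFB1 (-1.47 ± 0.11). Of the endoplasmic reticulum stress genes 9 of 9 fell (9 adjusted over the list alone, median -0.72, adjusted p = 6.96e-15), as with BIP2 (-1.02 ± 0.071) and ERDJ3B (-0.93 ± 0.075). For jasmonate 15 of 21 fell (18 adjusted over the list alone, median -1.41, adjusted p = 8.51e-05, adjusted p = 0.407 with an estimated correlation), as with LOX2 (-1.41 ± 0.22). For defensins 8 of 10 fell (8 adjusted over the list alone, median -1.50, adjusted p = 4.88e-06, adjusted p = 0.0788 with an estimated correlation), as with PR4 (-1.62 ± 0.14). In indolic glucosinolate and camalexin synthesis 7 of 14 fell (10 adjusted over the list alone, median -0.57, adjusted p = 0.000786, adjusted p = 0.146 with an estimated correlation), as with PAD3 (-2.66 ± 0.32). Of the flavonoid genes 2 of 19 rose and 9 fell (2 and 11 adjusted over the list alone, median -0.74, adjusted p = 0.0188, adjusted p = 0.492 with an estimated correlation), as with MYB12 (-1.33 ± 0.29). In the heat shock list 4 of 14 fell (4 adjusted over the list alone, median -0.49, adjusted p = 0.0389, adjusted p = 0.302 with an estimated correlation), as with HSP90.1 (-0.85 ± 0.17). With AT1G53540 at its bound the median was -0.34. Of the oxidative stress genes 7 of 12 fell (8, and 1 rose, adjusted over the list alone, median -0.49, adjusted p = 8.73e-06, adjusted p = 0.0660 with an estimated correlation), as with ZAT12 (-2.44 ± 0.19). Of the senescence genes 2 of 13 rose and 6 fell (2 and 6 adjusted over the list alone, median -0.65, adjusted p = 0.0389, adjusted p = 0.174 with an estimated correlation), as with WRKY53 (-3.01 ± 0.28).

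The photosynthesis list was higher than in ref4-3, as 18 of 23 rose (21 adjusted over the list alone, median 0.66, adjusted p = 6.33e-23, adjusted p = 0.0737 with an estimated correlation). In the cold and abscisic acid list 14 of 15 rose (14 adjusted over the list alone, median 1.12, adjusted p = 7.46e-19), as with COR47 (1.42 ± 0.060). Of the clock genes 9 of 16 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.38, adjusted p = 0.000310), as with PRR5 (0.94 ± 0.062) and PRR7 (0.91 ± 0.076). For auxin response 10 of 18 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.95, adjusted p = 1.34e-05, adjusted p = 0.0706 with an estimated correlation), as with IAA14 (1.49 ± 0.15). For cell expansion 7 of 14 rose and 2 fell (8 and 3 adjusted over the list alone, median 0.21, adjusted p = 0.0209, adjusted p = 0.385 with an estimated correlation), as with EXPA11 (1.54 ± 0.12). Of the xylem markers 6 of 13 rose (6 adjusted over the list alone, median 0.40, adjusted p = 0.0188, adjusted p = 0.254 with an estimated correlation), as with XCP1 (1.55 ± 0.19). Of the flowering time genes 4 of 10 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.0454, adjusted p = 0.138 with an estimated correlation), as with MAF4 (1.84 ± 0.28). Of the phosphate starvation genes 3 of 5 rose (4 adjusted over the list alone, median 0.38, adjusted p = 0.0188, adjusted p = 0.174 with an estimated correlation), as with SPX1 (0.96 ± 0.13). The salicylic acid, endoplasmic reticulum, cold and clock lists kept an adjusted p under 0.05 with an estimated correlation.

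Of the 7544 genes changed in ref4-3, 2741 (36.3%) changed the opposite way from ref4-3 to the double mutant, towards or past WT, 806 (10.7%) moved further from WT and 3997 (53.0%) were not called. The median ratio of the double mutant change to the ref4-3 change was 0.679 (jackknife SE 0.0663). In simulations of a double mutant equal to ref4-3 a mean of 0.4 genes were opposite and the ratio was 0.959. In the double mutant 4299 were still called on the ref4-3 side of WT and 468 on the other. These include cdk8-1's own effects.

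**Figure D3:**
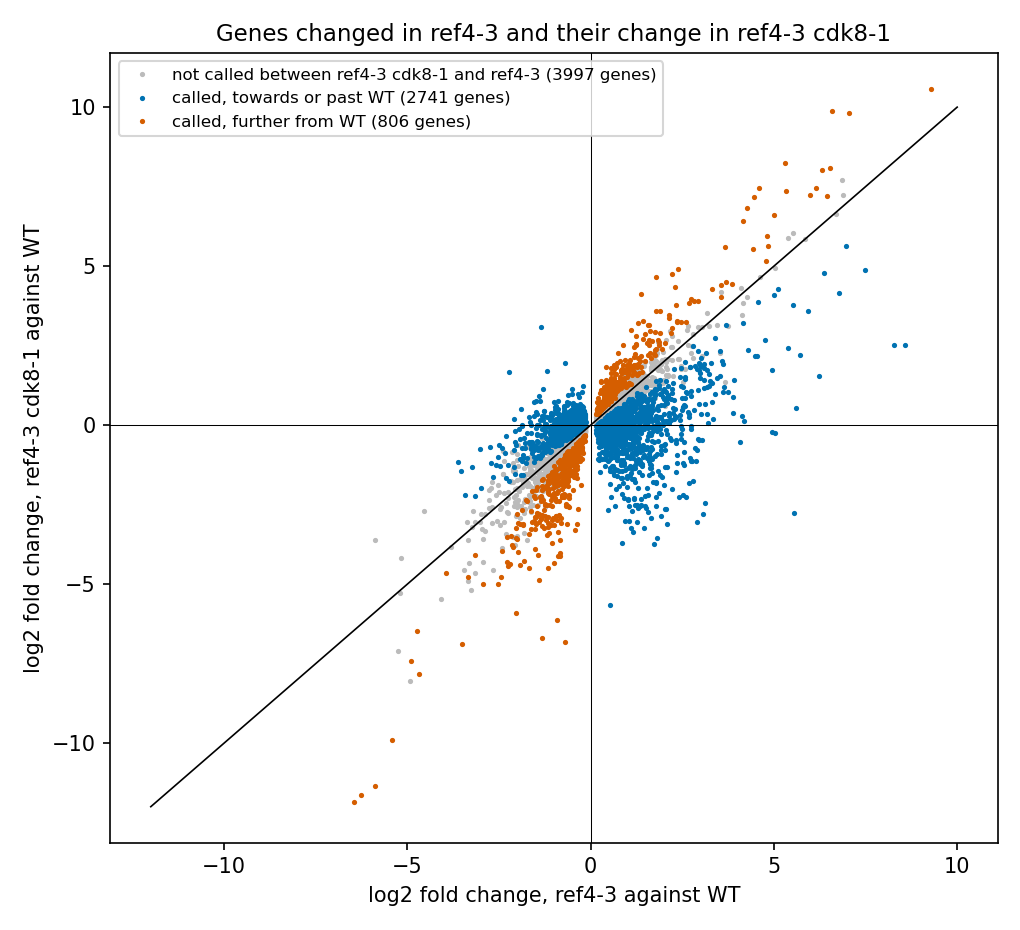
Log2 fold change of ref4-3 against WT (horizontal axis) and of ref4-3 cdk8-1 against WT (vertical axis) for the 7544 genes changed in ref4-3, with the diagonal marking equal change. Blue marks 2741 genes that moved towards or past WT, orange 806 that moved further and grey 3997 with no call between the mutants.

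Comparing ref4-3 cdk8-1 with cdk8-1 asked what ref4-3 changes where CDK8 is missing. KFB39, DJC66 and UGT84A2 rose, by 4.24 ± 0.12, 4.14 ± 0.11 and 1.57 ± 0.085, and CAD4 (-1.26 ± 0.079) and 4CL1 (-1.11 ± 0.074) fell. Cold and abscisic acid genes rose, with RD29A (2.36 ± 0.086) and ERD10 (1.299 ± 0.068). The salicylic acid list did not pass: 2 of 30 rose and 3 fell (2 and 2 adjusted over the list alone), the members with the smallest adjusted p being EDS5 (-1.60 ± 0.16), PR5 (1.84 ± 0.35) and WRKY38 (-1.48 ± 0.39; list median -0.10, adjusted p = 0.218). In all 6185 genes were called (3092 higher, 3093 lower), 1016 of them 2-fold.

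MRD1 was higher than in cdk8-1 by a count ratio of 1082 (95% counting interval 194 to 42751), back at 31.8 ± 0.467 CPM, followed by DAA1 (7.46 ± 0.31) and RD29B (7.22 ± 0.33). The greatest falls were MDHAR (-4.01 ± 0.80), PDF1.2A (-3.79 ± 0.70) and AT3G16670 (-3.37 ± 0.33). In the phenylpropanoid list 1 of 21 rose and 15 fell (1 and 16 adjusted over the list alone, median -0.54, adjusted p = 4.36e-11). For Kelch F-box genes 4 of 5 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.83, adjusted p = 3.60e-07). Of the flavonoid genes 6 of 19 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.70, adjusted p = 0.00214, adjusted p = 0.418 with an estimated correlation), as with FLS1 (1.04 ± 0.12). MYB11 had a count ratio of 27.4 (95% counting interval 7.30 to 230.5). In the cold and abscisic acid list 14 of 15 rose (14 adjusted over the list alone, median 2.13, adjusted p = 4.56e-40). Of the flowering time genes 6 of 10 rose (6 adjusted over the list alone, median 0.43, adjusted p = 0.00491), as with SOC1 (0.57 ± 0.060). Of the senescence genes 7 of 13 rose (7 adjusted over the list alone, median 0.54, adjusted p = 4.96e-05), as with ORE1 (2.74 ± 0.21).

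Lower than in cdk8-1 was the photosynthesis list, where 21 of 23 fell (23 adjusted over the list alone, median -0.55, adjusted p = 2.45e-13, adjusted p = 0.160 with an estimated correlation), as with RCA (-0.84 ± 0.083). Of the cell cycle genes 14 of 17 fell (14 adjusted over the list alone, median -0.46, adjusted p = 1.20e-06), as with PCNA1 (-0.54 ± 0.080). For jasmonate 12 of 21 fell (17 adjusted over the list alone, median -1.26, adjusted p = 1.69e-05, adjusted p = 0.418 with an estimated correlation), as with VSP1 (-2.51 ± 0.45). For defensins 1 of 10 rose and 5 fell (1 and 6 adjusted over the list alone, median -1.80, adjusted p = 0.00207, adjusted p = 0.239 with an estimated correlation), as with ORA59 (-1.79 ± 0.26). In indolic glucosinolate synthesis 8 of 14 fell (8 adjusted over the list alone, median -0.60, adjusted p = 0.000672, adjusted p = 0.160 with an estimated correlation), as with CYP83B1 (-0.94 ± 0.15). In aliphatic glucosinolate synthesis 2 of 14 rose and 9 fell (2 and 9 adjusted over the list alone, median -0.25, adjusted p = 0.0243, adjusted p = 0.418 with an estimated correlation), as with MAM3 (-0.78 ± 0.095). Of the auxin response genes 1 of 18 rose and 11 fell (1 and 12 adjusted over the list alone, median -0.73, adjusted p = 0.000422, adjusted p = 0.143 with an estimated correlation), as with SAUR24 (-1.71 ± 0.26). Of the cell expansion genes 1 of 14 rose and 9 fell (1 and 9 adjusted over the list alone, median -0.46, adjusted p = 0.00135, adjusted p = 0.264 with an estimated correlation), as with XTH4 (-0.46 ± 0.082). For endoplasmic reticulum stress 1 of 9 rose and 5 fell (1 and 5 adjusted over the list alone, median -0.35, adjusted p = 0.0364, adjusted p = 0.418 with an estimated correlation), as with CNX1 (-0.47 ± 0.074). Here 6 lists kept an adjusted p under 0.05 with an estimated correlation.

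The interaction asked whether the double mutant departs from the sum of the single mutant effects. Salicylic acid genes lay below that sum, SARD1 (-1.83 ± 0.22), EDS5 (-1.32 ± 0.20) and ICS1 (-1.37 ± 0.20), the isochorismate synthase of the pathway. Light-harvesting LHCB2.1 (0.92 ± 0.11), LHCB2.2 (0.89 ± 0.11) and LHCB1.2 (0.83 ± 0.11) lay above it. The chaperone HSP70 (2.197 ± 0.23) lay above and BIP2 (-0.80 ± 0.10) below. In all 1002 genes were called (619 above the sum, 383 below), 204 of them 2-fold. This count depended on single libraries, being 579 without cdk8-1 replicate 2 and 1431 without ref4-1 replicate 3.

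MRD1, with 1 count in cdk8-1, was called above the sum, and so were AT3G57880 (6.49 ± 0.22) and the glycosyl hydrolase AT4G16260 (3.78 ± 0.38). Below it were ARD3 (-3.45 ± 0.60), ATGLR1.2 (-3.08 ± 0.66) and ELIP1 (-2.74 ± 0.52). In the salicylic acid list 12 of 30 were called lower (19 adjusted over the list alone, median -0.91, adjusted p = 1.58e-21). In the phenylpropanoid list 2 of 21 were called higher and 3 lower (6 and 5 adjusted over the list alone), with SNG1 (0.84 ± 0.096) and UGT84A2 (-1.02 ± 0.12; list median 0.065, mean -0.015, adjusted p = 0.981). Among Kelch F-box genes 3 of 5 were called lower (3 adjusted over the list alone, median -0.46, adjusted p = 0.00338, adjusted p = 0.233 with an estimated correlation), as with KFB39 (-0.88 ± 0.18). For flavonoids 3 of 19 were called lower (4 adjusted over the list alone, median -0.99, adjusted p = 1.24e-08, adjusted p = 0.180 with an estimated correlation), as with F3H (-1.34 ± 0.26). The median was -1.02 without AT1G66390, at 0 in cdk8-1. In endoplasmic reticulum stress 7 of 9 were called lower (8 adjusted over the list alone, median -0.56, adjusted p = 1.80e-13), as with ERDJ3B (-0.68 ± 0.11). Of the cell cycle genes 4 of 17 were called lower (6 adjusted over the list alone, median -0.31, adjusted p = 2.69e-06), as with MCM7 (-0.56 ± 0.13). Of the aliphatic glucosinolate genes 1 of 14 was called lower (1 adjusted over the list alone, median -0.14, adjusted p = 0.0269, adjusted p = 0.416 with an estimated correlation), which was MAM3 (-0.69 ± 0.14). The jasmonate list was lower (median -0.42, adjusted p = 0.0483, adjusted p = 0.652 with an estimated correlation) with no member called by edgeR, 1 lower at an unadjusted p under 0.05, and 0 called by DESeq2 or voom.

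Above the sum lay the photosynthesis list, where 10 of 23 were called higher (11 adjusted over the list alone, median 0.37, adjusted p = 3.56e-11, adjusted p = 0.233 with an estimated correlation). In cell expansion 3 of 14 were called higher and 1 lower (5 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0164, adjusted p = 0.406 with an estimated correlation), as with EXPA11 (0.92 ± 0.17) and XTH17 (2.09 ± 0.52). In auxin response 2 of 18 were called higher and 1 lower (5 and 1 adjusted over the list alone, median 0.50, adjusted p = 0.0164, adjusted p = 0.305 with an estimated correlation), as with IAA2 (0.51 ± 0.13). For cold and abscisic acid 5 of 15 were called higher (7, and 1 lower, adjusted over the list alone, median 0.60, adjusted p = 9.46e-06, adjusted p = 0.153 with an estimated correlation), as with RD29A (0.77 ± 0.12). Of the clock genes 4 of 16 were called higher (5 adjusted over the list alone, median 0.30, adjusted p = 0.000162), as with ELF4 (0.81 ± 0.12). Of the flowering time genes 2 of 10 were called higher (2 adjusted over the list alone, median 0.46, adjusted p = 0.00123), as with MAF4 (2.35 ± 0.43). In the heat shock list 1 of 14 was called higher (2 adjusted over the list alone, median 0.56, adjusted p = 0.00139, adjusted p = 0.177 with an estimated correlation), which was HSP70. The median was 0.52 without AT1G53540. Among defensin genes 1 of 10 was called higher (1 adjusted over the list alone, median 0.82, adjusted p = 0.0164, adjusted p = 0.340 with an estimated correlation), which was PR4 (0.99 ± 0.19). The salicylic acid, cell cycle, endoplasmic reticulum, clock and flowering lists kept an adjusted p under 0.05 with an estimated correlation.

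**Figure D4:**
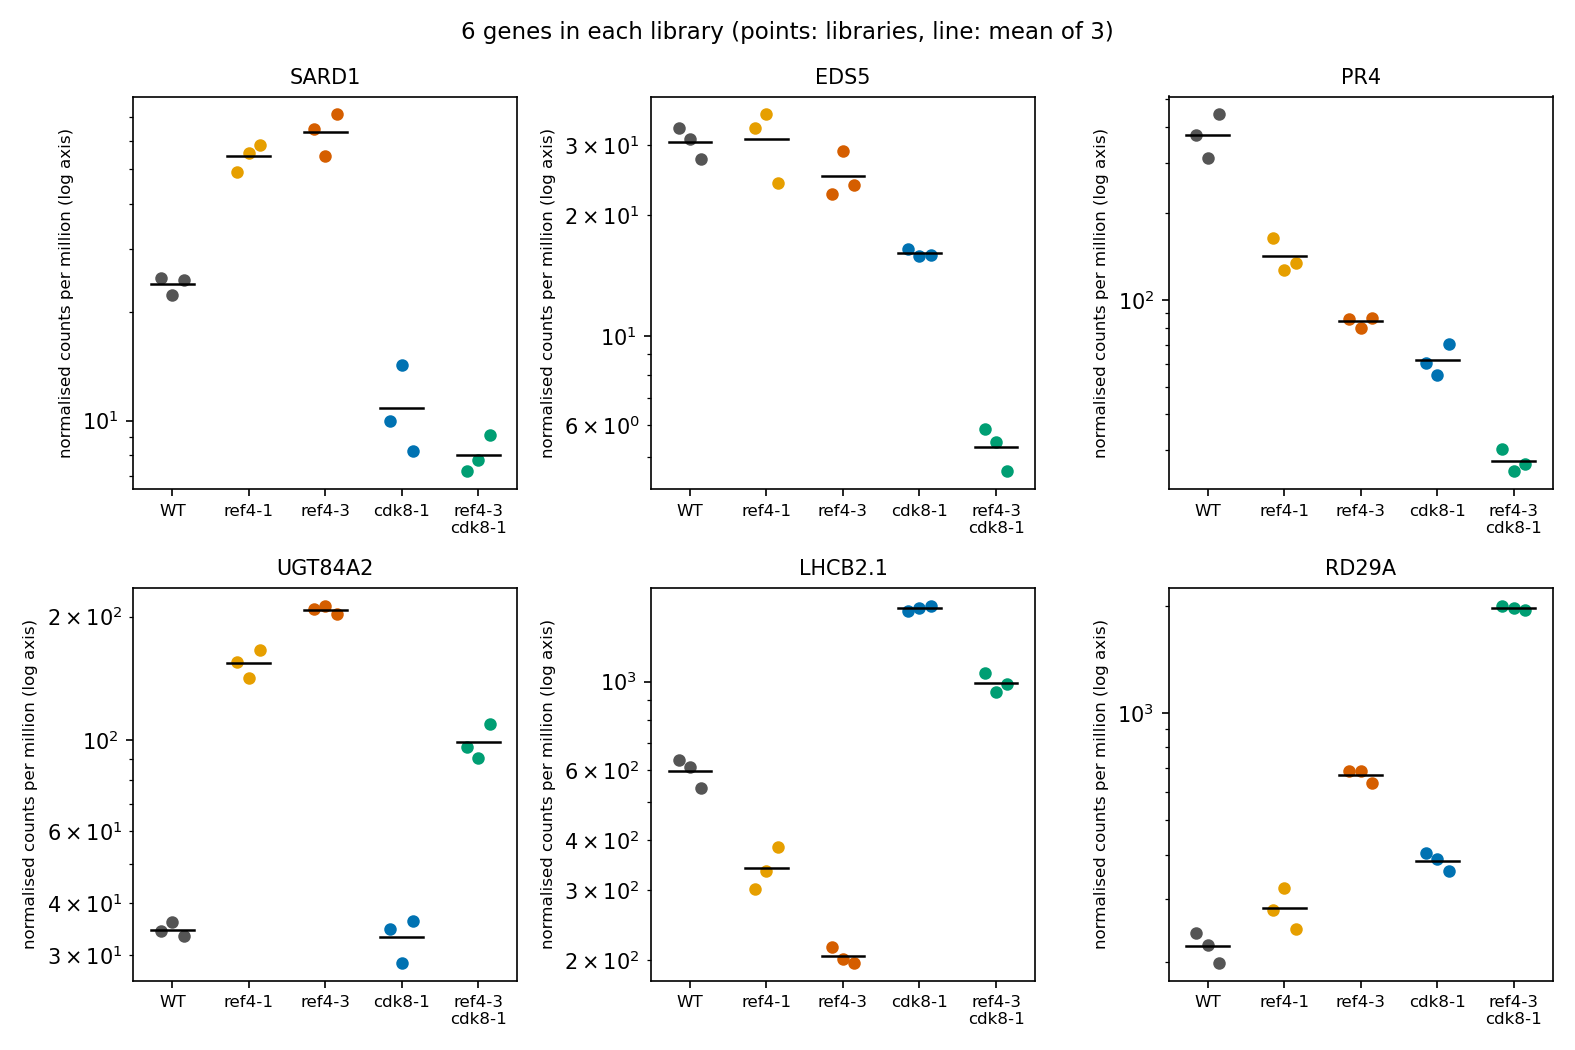
Normalised CPM on a log axis of SARD1, EDS5, PR4, UGT84A2, LHCB2.1 and RD29A in the 15 libraries by genotype, with points for libraries and lines for means of 3. SARD1 was 24.0 ± 1.42 CPM in WT, 63.4 ± 8.46 in ref4-3 and 8.03 ± 0.986 in ref4-3 cdk8-1.

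Of the Mediator subunit genes in ref4-3 against WT, 4 of 26 rose (2 adjusted over the list alone), as with MED16 (0.37 ± 0.086) and MED12 (0.33 ± 0.090; adjusted p = 0.369). In cdk8-1 1 of 26 fell (1 adjusted over the list alone), which was CDK8 itself (adjusted p = 0.650). In the double mutant 2 of 26 rose and 2 fell (2 and 1 adjusted over the list alone; adjusted p = 0.947). In ref4-1 edgeR, DESeq2 and voom called 0 of them, with 2 higher at an unadjusted p under 0.05 in edgeR (adjusted p = 0.858). Of the reference genes 2 of 6 fell (2 adjusted over the list alone) in the double mutant (adjusted p = 0.182), which were ACT2 (-0.60 ± 0.060) and UBC9 (-0.35 ± 0.057). Both also fell in ref4-3 (-0.47 ± 0.060 and -0.35 ± 0.058) and ref4-1 (-0.34 ± 0.060 and -0.22 ± 0.057), UBC9 without a call in ref4-1 when only its and the WT libraries were fitted. Of the iron genes 4 of 7 rose and 3 fell (4 and 3 adjusted over the list alone) in the double mutant (median 0.36, mean 0.035, adjusted p = 0.584), the ferritin gene FER4 (-0.92 ± 0.11) falling. Phloem and guard cell markers did not pass in any comparison, with SEOR1 (-0.89 ± 0.10) and SUC2 (0.54 ± 0.081) called in the double mutant (adjusted p = 0.947 for the list). Of 6 flower organ markers only AG was measured, and it fell in ref4-1, ref4-3 and the double mutant against WT (-1.89 ± 0.52, -2.12 ± 0.54 and -1.44 ± 0.48). Root and seed storage markers had no measured member. The median, mean and test of some lists that did not pass differed in sign. They were Mediator in ref4-1 and the double mutant against WT, phosphate starvation in ref4-1, ref4-3 and the interaction, clock in ref4-3, and iron in ref4-3 and cdk8-1. Others were auxin response in the double mutant against WT and phenylpropanoids in cdk8-1, the double mutant against ref4-3 and the interaction. Between the alleles they were the salicylic acid, Kelch F-box, heat shock, flowering and phloem lists.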

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

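All tests of explanations in this part were chosen after the results were seen, except the splits of the libraries and the test of the genes next to both silent genes. The results here come from the interaction of ref4-3 and cdk8-1, where the effect of ref4-3 differed with and without CDK8 (edgeR adjusted p under 0.05, n = 3 per group), and from reads outside the gene counts. The interaction called 1002 genes, or 579 without cdk8-1 replicate 2, and 4 of 100 drawn splits of the 12 libraries, the real one included, gave at least 1002. The highest other split gave 2475, which points to a structure of the samples. A split that mixes genotypes can carry their differences into the interaction, so these splits are no measure of chance, and whether chance can be excluded stays open. For the 6 comparisons of 3 with 3 other than that of the alleles, 1 of 10 splits, the real one, gave as many genes (3975, 7544, 3712, 8053, 6183 and 6185), and the highest other gave 0 by edgeR, with 791 to 2581 at an unadjusted p under 0.05. For ref4-3 against ref4-1 the real split gave 2095 genes and the highest other 100, and 10 splits are too few for a share under 0.05.

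Lists below the sum of the single effects had median log2 interactions of -0.91 for salicylic acid, -0.99 for flavonoids, -0.46 for Kelch F-box genes, -0.42 for jasmonate, -0.14 for aliphatic glucosinolates, -0.31 for the cell cycle and -0.56 for endoplasmic reticulum stress. Lists above it had 0.82 for defensins, 0.37 for photosynthesis, 0.13 for cell expansion, 0.50 for auxin response, 0.56 for heat shock, 0.60 for cold and abscisic acid, 0.30 for the clock and 0.46 for flowering time. A low-count floor was not tested for defensins. With an estimated correlation 5 lists kept an adjusted p under 0.05: salicylic acid, cell cycle, endoplasmic reticulum stress, clock and flowering time. The jasmonate list had no call and was lost with the replicate block (adjusted p = 0.0639). Genes below 0 were ARD3 (-3.45), ATGLR1.2 (-3.08), ELIP1 (-2.74), SARD1 (-1.83), EDS5 (-1.32), ICS1 (-1.37), UGT84A2 (-1.02), 4CL3 (-0.98), and FLS1 (-0.91). Also below 0 were F3H (-1.34), TT4 (-1.20), KFB50 (-0.46), KFB39 (-0.88), KFB1 (-0.81), MAM3 (-0.69), EXPA10 (-0.50), GH3.6 (-0.65), MCM7 (-0.56), PCNA1 (-0.47), CDC20.1 (-0.60), BIP2 (-0.80), ERDJ3B (-0.68) and BIP1 (-0.58). Genes above 0 were AT3G57880 (6.49), AT4G16260 (3.78), SNG1 (0.84), PR4 (0.99), LHCB2.1 (0.92), LHCB2.2 (0.89), LHCB1.2 (0.83), and EXPA11 (0.92). Also above 0 were XTH17 (2.09), IAA2 (0.51), IAA3 (0.40), HSP70 (2.197), COR47 (0.60), RD29A (0.77), ERD10 (0.60), ELF4 (0.81), LUX (0.46), PRR5 (0.37), MAF4 (2.35) and SOC1 (0.39). MRD1 had 9.59, which depends on the prior count since cdk8-1 left 1 count.

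Reads that overlapped no feature were 1.05% of the gene counts in ref4-1 replicate 3, above the highest WT library at 0.758%. Reads not uniquely placed were 6.62% there and 5.88% in cdk8-1 replicate 1, against at most 3.01% in WT. Ambiguous reads reached 6.67% in ref4-3 replicate 2, against at most 5.50% in WT.

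MRD1 and AT3G57880 were nearly silent in cdk8-1 but not in ref4-3 cdk8-1, though both carry cdk8-1. CDK8 argues against swaps with WT (at most 6.58 CPM here, at least 18.02 in WT). DJC66 does so for swaps between the mutants (at most 12.9 CPM in cdk8-1, at least 207.6 in the other). Loss of CDK8 cannot be told apart, as the smaller log2 difference, 6.73, is the pattern and ref4-3 may undo its effect. A deletion that takes in neighbours is argued against for AT3G57880, where the lowest change of the 4 nearest tested genes was -0.24 (SCE1), and for the 3 genes near MRD1 that do not overlap it (lowest -0.34, AT1G53460), but cannot be told apart for MRD1 with HEI10, which overlaps it, may share its reads and changed by -1.51. A difference carried by the cdk8-1 line outside CDK8 may remain for AT3G57880, but MRD1 was also low in ref4-1 (0.791 ± 0.780 CPM against 29.0 ± 2.05 in WT), which does not carry cdk8-1, so one peculiar to cdk8-1 would not cover both lines, and no further explanation was tested.

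Salicylic acid genes lay below the sum of the single effects in the double mutant. The 20 members with a mean of at least 10 CPM had a median interaction of -1.05 and 10 were called. A low-count floor in cdk8-1 was not tested. A candidate explanation is that the rise in ref4-3 requires CDK8. The 21 members that rose in ref4-3 (median 1.09, range 0.19 to 3.05) had a median of -0.065 between ref4-3 cdk8-1 and cdk8-1 (range -1.48 to 3.44), 2 of them called higher and 1 lower. This is a hypothesis found and tested on the same libraries, and plant size or stage, which were not measured here, may differ too.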

How the results depend on the processing

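Leaving out ref4-1 replicate 3 from comparisons without ref4-1 was chosen after the data were seen, and the other alternatives before. Of 306 main values under alternatives, 272 stayed within 1.5 times the count or 1 jackknife SE from left-out libraries and 34 moved. Of 8681 values of named genes under alternatives, 8355 kept their side of the threshold and direction, 292 lost the call and 34 gained one. With another tool, scaling, filter or block at least 81.5% of calls were kept and the share of higher calls moved at most 4.90 points. Left-out libraries included, the median log2 fold change of all genes lay between -0.00394 and 0.0269.

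With a 2-fold minimum the calls were 784 in ref4-1, 1490 in ref4-3, 888 in cdk8-1 and 1854 in ref4-3 cdk8-1 against WT, 1413 and 1016 in ref4-3 cdk8-1 against ref4-3 and cdk8-1, 204 for the interaction and 187 between the alleles. The overlap of ref4-1 and ref4-3 changes was then 703 and the overlap of cdk8-1 and ref4-3 changes 170. Of the ref4-3 changes, 493 were opposite in the double mutant, as fewer genes pass. With an estimated correlation 2, 2, 7, 3, 4, 6, 5 and 1 lists passed in the order ref4-1, ref4-3, cdk8-1 and double mutant against WT, double mutant against ref4-3 and cdk8-1, interaction, and alleles, against 15, 13, 14, 15, 18, 15, 15 and 8 with the preset one. The mixed fry test, which asks only whether members change, passed 23 lists in ref4-1, 25 in ref4-3, 24 in cdk8-1 and 25 in the double mutant against WT, 24 for the double mutant against cdk8-1 and 17 between the alleles, and the directional one 20 in ref4-3. Only the compared groups in the fit gave 823 calls between the alleles, and with no filter the correlation was 0.690 for ref4-1 with ref4-3 and 0.278 for cdk8-1 with ref4-3. The cause was not tested for these.

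Leaving out 1 library gave 3066 to 4018 calls in ref4-1, 6201 to 8087 in ref4-3, 2734 to 4214 in cdk8-1, 6572 to 8584 in the double mutant against WT, 5105 to 6742 against ref4-3 and 5031 to 6732 against cdk8-1. The interaction had 579 (without cdk8-1 replicate 2) to 1431 (without ref4-1 replicate 3), with 637 without WT replicate 2 and 648 without ref4-3 replicate 3. Between the alleles it was 1040 (without ref4-3 replicate 3) to 2061. The lists past camera numbered 12 to 16, 12 to 14, 13 to 15, 13 to 16, 15 to 18, 13 to 16, 13 to 15 and 6 to 11 in the order above. The overlaps were 2692 to 3683 and 743 to 969, the opposite changes 2045 to 2682, their median ratio 0.633 to 0.714, and the correlations 0.854 (without ref4-1 replicate 2) to 0.903 and 0.0361 to 0.0906. The highest counts of calls, all without ref4-1 replicate 3 except between the alleles, lay above the main ones in every comparison but that one. The cause was not tested.

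Of 113 list results past camera, 20 had an adjusted p of 0.05 or more without 1 library, given here as genotype and replicate number. For ref4-1 this held for aliphatic glucosinolates (0.0594 without WT 1, 0.0850 WT 2, 0.0511 ref4-1 1, 0.0875 ref4-1 3). Xylem had 0.0574 without WT 1, 0.108 ref4-1 3. Heat shock had 0.137 without WT 1, 0.0745 ref4-1 3. For ref4-3 this held for jasmonate (0.0546 without ref4-3 1). For cdk8-1 this held for flavonoids (0.157 without WT 3). For the double mutant against WT this held for cell expansion (0.0677 without WT 2, 0.0858 ref4-3 cdk8-1 2). Cell cycle had 0.0560 without WT 2, 0.0565 WT 3, 0.0664 ref4-3 cdk8-1 1. For the double mutant against ref4-3 this held for flavonoids (0.0790 without ref4-3 2, 0.0522 ref4-3 cdk8-1 1). Flowering time had 0.0556 without ref4-3 2, 0.0839 ref4-3 cdk8-1 2. Senescence had 0.0603 without ref4-3 2, 0.0653 ref4-3 cdk8-1 2. Heat shock had 0.0664 without ref4-3 cdk8-1 2. For the double mutant against cdk8-1 this held for aliphatic glucosinolates (0.0531 without cdk8-1 1, 0.0710 ref4-3 cdk8-1 1). Endoplasmic reticulum stress had 0.0783 without cdk8-1 3, 0.0758 ref4-3 cdk8-1 1, 0.0515 ref4-3 cdk8-1 2. For the interaction this held for auxin response (0.0712 without WT 2, 0.121 ref4-3 1). Jasmonate had 0.332 without WT 3, 0.550 ref4-3 2, 0.0897 cdk8-1 1, 0.165 cdk8-1 3, 0.164 ref4-3 cdk8-1 1, 0.0931 ref4-3 cdk8-1 2. Aliphatic glucosinolates had 0.211 without ref4-3 2, 0.0897 cdk8-1 1, 0.112 ref4-3 cdk8-1 1. Cell expansion had 0.0615 without cdk8-1 2. Defensins had 0.0942 without ref4-3 cdk8-1 3. For the alleles this held for jasmonate (0.0652 without ref4-1 1, 0.0592 ref4-3 1). Auxin response had 0.0652 without ref4-1 1, 0.0592 ref4-3 1.

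Libraries with the same replicate number did not deviate together, with a mean correlation of 0.0212 over 30 pairs, 7 of them above 0.1, and 6 of 15 libraries correlated best with their own number. As a check only, a replicate block gave 4108, 7675, 3800, 8134, 6269, 6290, 1098 and 2271 calls in the order above. With the block 3 list results did not pass, aliphatic glucosinolates in ref4-1 (adjusted p = 0.0544), flowering time in the double mutant against ref4-3 (0.0560) and jasmonate for the interaction (0.0639), and no other list or count was lost. At 1 count per 0.0595 to 0.104 CPM, 8726 genes had no count, and whether depth is the cause was not tested. In simulation 37.3% of 1.5-fold interactions were recovered.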

Other observations

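The tests of product families and of jasmonate genes against the share of reads not uniquely placed were chosen after the results were seen. The 14 product families of the annotation were compared with other genes by camera, adjusted over the families. Aquaporin genes, the water channels, fell in both ref4 alleles: 2 of 23 rose and 13 fell (median -0.55, adjusted p = 6.44e-07, adjusted p = 0.367 with an estimated correlation) in ref4-3. In ref4-1 1 of 23 rose and 12 fell (median -0.44, adjusted p = 9.84e-07, adjusted p = 0.550 with an estimated correlation). PIP2A (-1.41 ± 0.080) and PIP1A (-1.34 ± 0.065), chosen likewise, fell in ref4-3. In ref4-3 cdk8-1 against ref4-3 11 of 23 rose and 1 fell (median 0.14, adjusted p = 0.0106, adjusted p = 0.521 with an estimated correlation). Ribosomal protein genes fell by small amounts in ref4-3, where 6 of 276 rose and 147 fell (median -0.23, adjusted p = 1.47e-07, adjusted p = 0.556 with an estimated correlation).

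Of WRKY transcription factor genes, 22 of 51 rose and 4 fell (median 0.29, adjusted p = 0.00211, adjusted p = 0.367 with an estimated correlation) in ref4-3. In cdk8-1 2 of 51 rose and 21 fell (median -0.36, adjusted p = 1.11e-06, adjusted p = 0.132 with an estimated correlation). In the double mutant against ref4-3 3 of 51 rose and 30 fell (median -0.80, adjusted p = 1.15e-12, adjusted p = 0.0818 with an estimated correlation). Of cysteine-rich receptor kinase genes, 3 of 30 rose and 12 fell (median -0.58, adjusted p = 4.19e-06, adjusted p = 0.137 with an estimated correlation) in cdk8-1. Against ref4-3 3 of 30 rose and 21 fell (median -1.34, adjusted p = 6.45e-10, adjusted p = 0.0869 with an estimated correlation) in the double mutant. They did not pass in ref4-3, where 15 of 30 rose and 6 fell (median 0.36, adjusted p = 0.106, adjusted p = 0.770 with an estimated correlation).

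Jasmonate genes varied together between replicate libraries, with an SD within groups of 0.409 on the log2 scale, from -0.70 in ref4-1 replicate 3 to 0.53 in ref4-3 replicate 2. The next lists had 0.247 (flavonoids) and 0.238 (defensins). Thinning to the lowest total left a ratio of SDs of 1.01, which excludes nothing, as thinning keeps each gene's expected CPM. Sequencing depth, incomplete selection of polyadenylated RNA and a shared order of harvest stay open with this number of libraries. Across the 15 libraries the deviation correlated with the share of reads not uniquely placed at Pearson r = -0.399 (permutation p = 0.306) and Spearman rho = -0.279 (permutation p = 0.429), or r = -0.179 (p = 0.608) and rho = -0.0934 (p = 0.787) by permutation without ref4-1 replicate 3 and cdk8-1 replicate 1. Replicate number took 14.6% of the variance, against a mean of 20.0% (SD 16.5) over 7776 permutations (permutation p = 0.532), and no biological explanation was tested.

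Sequence differences linked to the mutated genes could change genes close to them, and this was a hypothesis set before the counts were seen. Within 1 Mb of CDK8, 20 of 459 tested genes changed 2-fold in cdk8-1 (4.36% against 4.70% elsewhere, odds ratio 0.923, 95% interval 0.555 to 1.45, exact Fisher p = 0.823). Near MED5B it was 17 of 233 in ref4-3 (7.30% against 7.90%, odds ratio 0.917, 0.523 to 1.51, exact Fisher p = 0.902) and 12 of 233 in ref4-1 (5.15% against 4.14%, odds ratio 1.26, 0.637 to 2.26, exact Fisher p = 0.407). The shares were not above those elsewhere in cdk8-1 and ref4-3, and for ref4-1 the interval leaves it open.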
